A study of Synechocystis sp. PCC 6803 with 11 samples.

How the data were processed

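The samples were total RNA of wild-type Synechocystis sp. PCC 6803, a unicellular cyanobacterium that cannot fix nitrogen gas and bleaches when combined nitrogen runs out. Per the labels, cultures were sampled during exponential growth, after 14 d without a nitrogen source, and 4, 12, 24 and 48 h after return to nitrate-containing medium. The series text gives 13 h where the sample titles give 12 h, and the titles' value is used throughout. There were 2 arrays for each of 5 groups and 1 array for 48 h, 11 arrays in all, and the series text calls the replicates biological. Per the labels' protocols, DNase-treated RNA was labelled directly with Cy3, without cDNA synthesis, so a probe reads the RNA strand complementary to it.

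Each scanner file held 1 array with 62334 spots, of which 1319 were controls and 61015 were probes. Per the file headers, the authors' spot intensity values came from Agilent Feature Extraction 10.7.3.1, which had subtracted background to give the processed intensity. The authors also deposited a table of log2 values for the whole series. Its column medians lay between 9.69 and 9.70 with a common minimum of 6.12 and maximum of 19.5, and its ranks followed each array's median spot intensity, so it holds quantile-normalized values. The submitters' processing notes name limma, with no version, and the exact steps are not given in the sources used here.

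Of the probes, 60866 carry a running number only, and 149 are named for a CRISPR array or a leader. The array files do not pair the numbered probes with genes, and no genome was used here. The 22 gene lists fixed before the data were examined held 305 distinct locus tags, of which 0 occurred in the array files and 0 in the reference table of 3347 genes for assembly ASM28445v1 (substrain PCC-P). The list tests were therefore not run, and the rule for named genes, written for gene symbols, could be applied to probes only: among called probes with both arrays of one group above both arrays of the other and the brighter group well above background on both arrays, the 2 that rose most and the 2 that fell most in starved cells are given. CRISPR and leader probes were chosen for description because they are the probes whose names say what they detect, after the array names were seen. The median of the kept probes formed 1 feature for each of CRISPR1, CRISPR2, CRISPR3, LEADER1 and LEADER2, and each other probe was its own feature.

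Analysis used R 4.3.3 with limma 3.58.1. The processed intensity was taken as log2 after removal of control spots and of 1 spot flagged as an outlier. Because 44.9% of the probes were well above background on all arrays, under the limit set beforehand, the 75th percentile of each array was taken over those 27391 probes and subtracted. A probe entered the fit if it was well above background on both arrays of at least 1 of the 5 groups with 2 arrays, which kept 47869 probes and gave 47770 features. One group-means model was fitted to all 11 arrays with lmFit and eBayes, with 5 residual degrees of freedom. The single 48 h array was assumed to vary like the other groups. P-values were two-sided and Benjamini-Hochberg adjusted within each of the 11 comparisons. A feature was called at an adjusted p under 0.05 with an absolute log2 change of at least 1. In simulated data for starved against growing cells over 47869 probes, 200 of them changed, the fit recovered 50% of changes of 1.5 log2, 78% of 2, 94% of 3 and 100% of 4, with 15 false calls. In the data 23024 features were called in that comparison, where the adjustment is less strict, so these rates need not hold there.

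A probe well above background on no array of a group has only a bound there. Its fold, and that of a named probe well above background on 1 of 2 arrays, is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Medians over called features in starved against growing cells take such probes at their bound. Features followed through recovery were restricted, after the data were seen, to probes well above background on all arrays, because in recovery both groups can be dim and a bound then has no direction. Precision is limited by the number of arrays.

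The growing and starved arrays shared slide 1 (4 arrays) and all recovery arrays shared slide 2 (7 arrays). Starved against growing and the steps within recovery were therefore compared within a slide. For recovery against starved or growing cells, slide and group cannot be told apart.

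Probe sequences were used to find complementary pairs, which share at least 25 bases on opposite strands and have no other partner, and to class probes by whether the target strand has a reading frame without a stop codon. Measures with 1 value per array were tested with an exact permutation test over all 10395 divisions of the 11 arrays into 5 pairs and 1 single array, with Benjamini-Hochberg adjustment over 5 measures. The divisions ignore slide.

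Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, median scaling, the 75th percentile over all probes, no filter, a filter on all 11 arrays, the mean of a feature's probes, the replicate number as a block, arrays of one slide alone, only the 2 groups compared, no minimum fold, an intensity trend in the prior, the deposited table, and each replicate left out. Subtraction of a signal level shared by both strands was added after the data were seen.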

Results

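Nitrogen starvation and recovery were followed on 11 arrays of 61015 probes. Growing cells, cells starved for 14 d, and cells at 4, 12 and 24 h of recovery each had 2 arrays, and 48 h had 1. Between 53.5% and 57.6% of probes were well above background in growing cells, 72.2% and 91.4% in starved cells, and from 55.8% to 77.1% during recovery. Replicate arrays correlated with Pearson's r from 0.960 at 12 h to 0.982 at 24 h over the fitted features. The numbered probes are not paired with genes here, so the CRISPR and leader features are the ones with names. CRISPR arrays are rows of repeats and spacers whose long transcript is cut into short guide RNAs against invading DNA, and a leader is the sequence in front of such an array.

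The first comparison asked what 14 d without nitrogen changed. The CRISPR1 feature rose in starved cells, from -0.80 ± 0.11 to 1.06 ± 0.02 (SD, n = 2, log2 signal relative to the array's 75th percentile), a log2 change of 1.86 with a standard error of 0.16 and an adjusted p of 8.09e-05 in limma. Of its 45 kept probes, 44 were higher in starved cells. Its 49 probes, kept or not, share their first and last bases and hold 45 distinct sequences. CRISPR2 changed the other way, from -0.77 ± 0.04 to -2.57 ± 0.11 (SD, n = 2), a log2 change of -1.81 with a standard error of 0.16 and a limma adjusted p of 8.07e-05. Its direction depended on the filter, and with no filter on dim probes its change was 0.46 and was not called, while over probes well above background on all arrays it was -3.18 and was called. LEADER2 fell from 2.71 ± 0.18 to -1.14 ± 0.58 (SD, n = 2), 14.4-fold, with a limma adjusted p of 3.83e-05. That feature rests on 2 kept probes of 3, both lower in starved cells. R_LEADER2-1, the probe left out, was well above background on 0 arrays. LEADER1 changed by -0.42, below the minimum fold. Of its 4 probes, 3 were lower, by -0.85, -1.09 and -1.03, and 1 was higher, by 0.18.

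The change varied with probe number in CRISPR2. The order of the probe numbers along the genome is not given in the sources used here. In growing cells the 17 kept probes of the first part of the numbering had a median level of 0.71, which was -1.97 in starved cells. Across the 26 kept CRISPR2 probes, the starvation change correlated with probe number with a Spearman's rho of 0.86. Over the 17 that were well above background on all 4 growing and starved arrays, a check added after the data were seen, rho was 0.78, and 15 of these were lower in starved cells. A probe near background cannot fall far, and its signal level was not separated from its number here. For CRISPR1 rho was 0.12 over 45 probes. The CRISPR3 feature had a log2 change of -0.0048 with an adjusted p of 0.987 in limma. Its first 19 kept probes went from a median of 0.60 to -0.60, and its other 8 from -3.96 to -3.11. Across the 27 kept CRISPR3 probes rho was 0.65, and 0.41 over the 18 well above background on all 4 growing and starved arrays. Over probes well above background on all arrays the CRISPR3 change was -1.53 and was called. Probes of one array are not independent replicates.

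**Figure D1:**
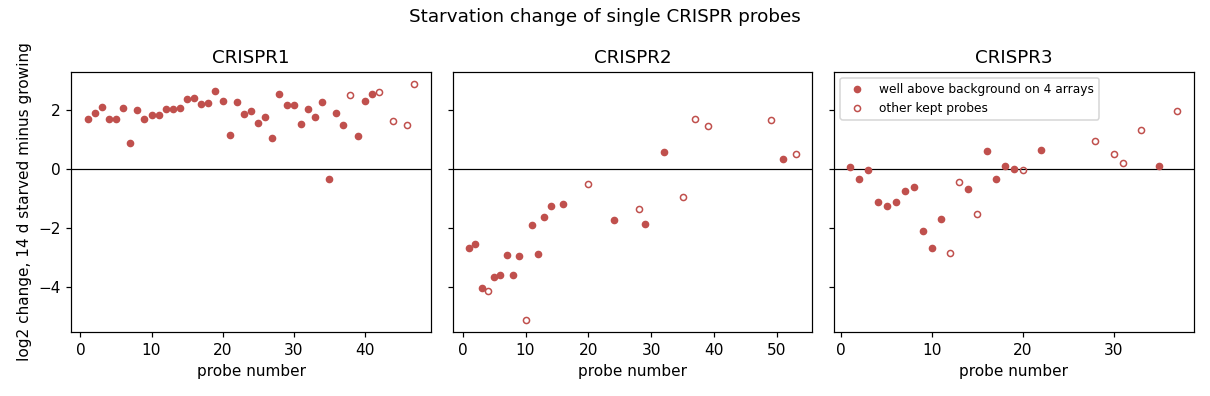
Log2 change from growing to 14 d starved cells (vertical axis) of each kept probe against the number in its name (horizontal axis). Filled points are probes well above background on all 4 arrays, and open points are the other kept probes. Of the filled points, 39 of 40 in CRISPR1 were higher in starved cells and 15 of 17 in CRISPR2 were lower.

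Over all features, 23024 of 47770 were called in starved against growing cells, 17398 higher and 5626 lower. Of the called single probes, 40.5% were not well above background on any array of the dimmer group. With such probes at their bound, the median log2 change was 1.27 among those higher and -1.65 among those lower. Features taken at a bound numbered 9164 of the 17398 higher and 165 of the 5626 lower. The probe SYN-CR-76-3422, with sequence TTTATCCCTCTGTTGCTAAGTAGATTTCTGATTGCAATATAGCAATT, was not well above background in growing cells and was at least 182-fold higher in starved cells (limma adjusted p = 3.95e-06). SYN-CR-76-2606, with sequence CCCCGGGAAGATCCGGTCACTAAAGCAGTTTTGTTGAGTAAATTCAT, was at least 159-fold higher (limma adjusted p = 2.33e-06). SYN-CR-76-50978, with sequence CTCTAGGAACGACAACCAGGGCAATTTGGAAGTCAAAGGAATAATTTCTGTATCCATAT, was at least 331-fold lower (limma adjusted p = 5.86e-05). SYN-CR-76-275, with sequence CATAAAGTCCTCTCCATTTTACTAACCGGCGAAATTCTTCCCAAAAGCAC, was at least 219-fold lower (limma adjusted p = 1.80e-05). In starved cells each of the last 2 was well above background on 1 array.

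The size of the split depended on scaling, on background correction and on the filter. The median log2 change of all features was 0.61, and 10959 features were called and rose by at least 1 above that shift. The share of called features that were higher was 75.6%, against 65.9% with median scaling, 61.9% with the 75th percentile over all probes and 52.0% after quantile normalization. It was 64.7% with normexp, 57.2% over probes well above background on all arrays and 77.3% with no filter. With a signal level shared by both strands subtracted, a setting that is not a scaling and was chosen after the data were seen, it was 45.4%. That setting subtracted levels of 242 and 396 on the starved arrays and 84.2 and 48.9 on the growing arrays, so it lowers this share by construction. Relative to the shift, CRISPR1 changed by 1.24, CRISPR2 by -2.42 and LEADER2 by -4.47.

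**Figure D2:**
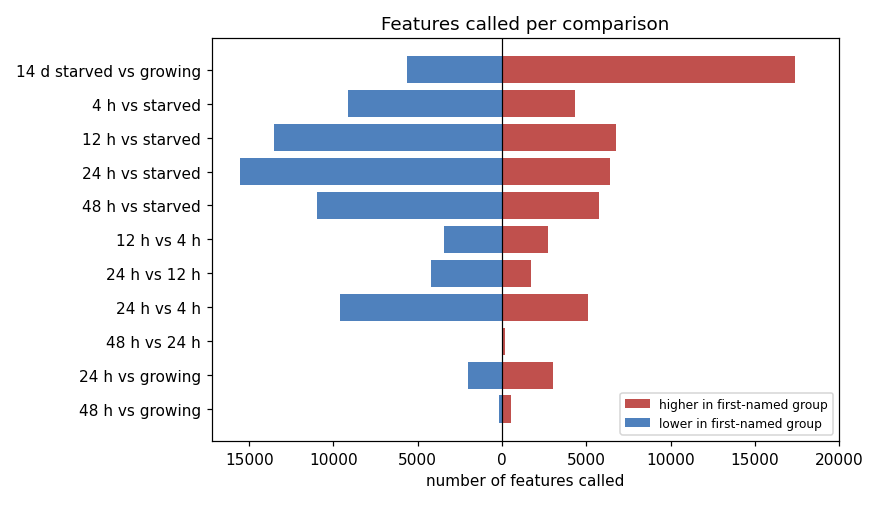
Number of features called (horizontal axis) in each of the 11 comparisons (vertical axis), with features higher in the first-named group to the right and lower to the left. Starved against growing had 17398 higher and 5626 lower, and 48 h against 24 h had 175 and 10.

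The second question was when the return of nitrogen changed these levels. At 4 h, none of the 5 named features was called against starved cells. The starved arrays lie on another slide, so slide and group cannot be told apart in the comparisons with them. CRISPR1 differed from starved cells by -0.23 and CRISPR2 by -0.10, with limma adjusted p of 0.279 and 0.635. LEADER1 had a log2 change of 0.83 at 4 h with a limma adjusted p of 0.00199, below the minimum fold. It was called with the percentile over all probes (1.03) and with the mean of its probes (1.21). The LEADER1 probes did not move alike. R_LEADER1-1, R_LEADER1-2 and R_LEADER1-3 went from 1.95, -0.56 and 1.01 in starved cells to 3.36, 1.21 and 2.63 at 4 h. R_LEADER1-4 went from 1.77 to 1.81. By 12 h LEADER2 had risen by 3.46 on the log2 scale from its 4 h level (limma adjusted p = 0.000293), and CRISPR2 had risen by 1.18 (limma adjusted p = 0.00231). CRISPR2 was not called in that step with no filter (0.95), with normexp (0.85) or in the deposited table (0.96). The steps from 4 to 12 h lie within slide 2.

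Between 4 and 24 h, within the same slide, CRISPR1 fell by 1.54 on the log2 scale, CRISPR2 rose by 1.79 and LEADER2 rose by 3.11, with limma adjusted p of 0.000277, 0.000123 and 0.000126. With no filter the CRISPR2 rise was 1.01, with a limma adjusted p of 0.183, and was not called. CRISPR3 fell by 1.45 over the same interval with a limma adjusted p of 0.0024, and was not called in that step with no filter (-0.33), with the strict filter (-0.72), with the mean of its probes (-0.73) or in the deposited table (-0.91).

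**Figure D3:**
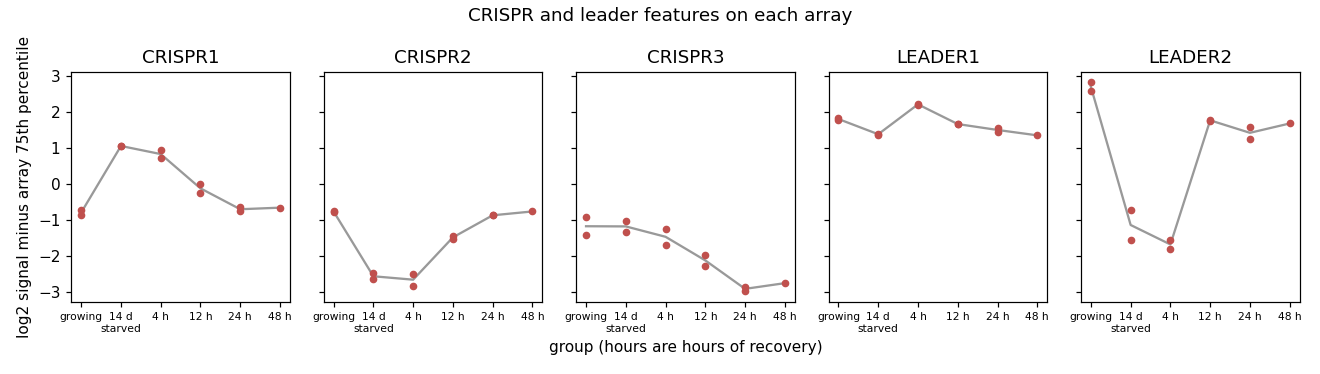
Log2 signal relative to the 75th percentile (vertical axis) of 5 features in each group (horizontal axis). Points are arrays and the line joins group means. CRISPR1 rose to 1.06 in starved cells and was at -0.71 by 24 h, and LEADER2 fell to -1.14 and was at 1.77 by 12 h.

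Among all features, 13455 were called at 4 h against starved cells (4345 higher, 9110 lower), 20276 at 12 h (6746 higher, 13530 lower), 21977 at 24 h (6410 higher, 15567 lower) and 16734 at 48 h (5748 higher, 10986 lower). After quantile normalization the higher share of calls was 49.5%, 48.1%, 49.3% and 50.9%, against 32.3%, 33.3%, 29.2% and 34.3%. The split turned at 4 h with the strict filter (3271 higher, 3233 lower), and with strandless signal subtracted at 4 h (7321 higher, 5486 lower) and 12 h (9565 higher, 8721 lower). The subtraction took most from the starved arrays, which favours the latter turns by construction. In the deposited table the higher share was 50.5%, 50.2%, 50.1% and 51.8%. These groups lie on different slides, so slide and group cannot be told apart. Within slide 2, 6137 features were called between 4 and 12 h (2716 higher, 3421 lower), 5975 between 12 and 24 h (1748 higher, 4227 lower) and 14677 between 4 and 24 h (5087 higher, 9590 lower). The direction of the 4 to 12 h step depended on scaling and on single arrays, with 3166 higher and 2962 lower with the percentile over all probes, 3262 higher and 2534 lower without 12 h replicate 1, and 2383 higher and 5437 lower without 12 h replicate 2. After quantile normalization the higher share was 45.3% against 29.3% for 12 to 24 h, and 47.1% against 34.7% for 4 to 24 h. Without 24 h replicate 1, the 12 to 24 h step had 3718 calls. It had 2745 higher and 3002 lower without 12 h replicate 2, and 1490 higher and 5579 lower without 12 h replicate 1.

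The third question was whether recovery undid the changes of starvation. Of the 23024 features called in starved cells, 83.4% had the opposite sign between 4 and 24 h of recovery, against 71.4% of all 47770 features. The log2 changes in starvation and from 4 to 24 h correlated across all features with a Pearson's r of -0.57, and their medians were 0.61 and -0.18. The comparisons share 0 arrays, and features are not independent replicates. Features higher in starved cells and then lower from 4 to 24 h numbered 6352, where independent lists would share 3493. Those lower and then higher numbered 2539, where independent lists would share 599.1. An array-wide measure also reversed. The median difference between complementary probes averaged 1.93 in growing and 1.54 in starved cells, and 1.82 at 4 h and 2.13 at 24 h. The counts for independent lists do not allow for this, and its part in the reversal was not separated. SYN-CR-76-3422 lay at 4.10 in starved cells, 3.30 at 4 h and -1.84 at 24 h. SYN-CR-76-2606 lay at 3.90 in starved cells and -0.60 at 4 h, and was not well above background at 24 h. SYN-CR-76-50978 was well above background on 1 array at 4 h and on 2 at 12 h, and SYN-CR-76-275 on 0 and 2. At 24 h SYN-CR-76-50978 lay at -0.30, below 2.07 at 12 h, and SYN-CR-76-275 at -1.03, below 1.06. On the single 48 h array they lay at 2.70 and 1.68. Against growing cells, on another slide, they differed at 24 h by log2 changes of -5.22 and -4.75 (limma adjusted p = 0.00573 and 0.00259). SYN-CR-76-3422 was still called higher than in growing cells at 24 h (limma adjusted p = 0.00106).

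Of the 17398 features that rose in starvation, 5700 were single probes well above background on all arrays. They stood at a median log2 difference from growing cells of 1.46 in starved cells, 0.88 at 4 h, 0.40 at 12 h, 0.19 at 24 h and 0.27 at 48 h. Of the 5626 that fell, 4265 were such probes, and they stood at -1.57, -0.96, -0.21, -0.10 and -0.12. All recovery values set slide 2 against growing cells on slide 1, so slide and group cannot be told apart in them.

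**Figure D4:**
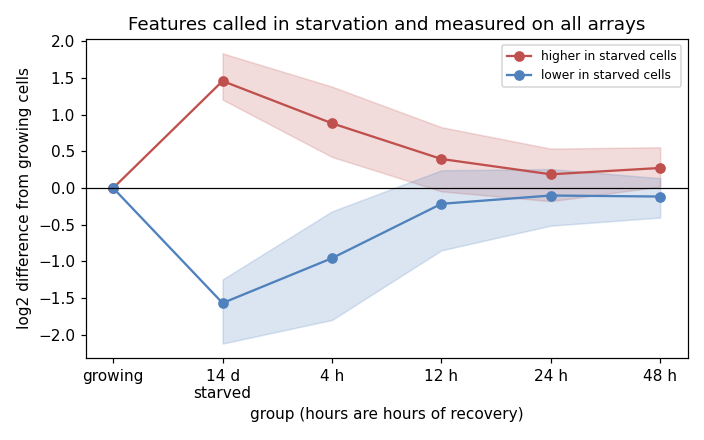
Median log2 difference from growing cells (vertical axis) in each group (horizontal axis) for probes called higher or lower in starved cells and well above background on all arrays. Shading spans the quartiles over features. The medians were 1.46 and -1.57 in starved cells and 0.19 and -0.10 at 24 h. Because both sets were chosen on the growing and starved arrays, part of the return comes with that choice. Recovery arrays lie on another slide than growing and starved arrays.

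The last comparisons set recovered cells beside growing cells, on different slides. At 24 h, CRISPR1 differed from growing cells by 0.09 and CRISPR2 by -0.11, with limma adjusted p of 0.702 and 0.648. The CRISPR2 difference ranged over the alternatives from -0.995, over probes well above background on all arrays (limma adjusted p = 0.000711, below the minimum fold), to 0.413 with no filter. CRISPR3 was lower by a log2 change of -1.75 (limma adjusted p = 0.00556), and LEADER2 by -1.28 (limma adjusted p = 0.0191). With no filter on dim probes the CRISPR3 change was -1.02 and was not called. The LEADER2 call was lost without either growing replicate and without either 24 h replicate, with changes from -1.44 to -1.13. Over all features, 5078 were called at 24 h, 3033 higher and 2045 lower. The higher share was 59.7%, against 48.5% after quantile normalization. Without 24 h replicate 1 the count was 1925, and without 24 h replicate 2 there were 1568 higher and 2104 lower.

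The single 48 h array differed from 24 h in 185 features, 175 higher and 10 lower, and from growing cells in 669, 511 higher and 158 lower. These counts moved with the spread that other groups lend the 48 h array, and without 4 h replicate 1 they were 17 and 34. The higher share against 24 h was 94.6%, and 81.4% after quantile normalization. Against growing cells it was 76.4%, and 63.3% after quantile normalization. CRISPR3 differed from growing cells by -1.59 at 48 h, with a limma adjusted p of 0.0546, and was called in 8 of 21 alternatives, with adjusted p from 0.00404 to 0.458.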

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

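The tests of strand, added signal, non-specific binding, scaling and slide below were chosen after the results were seen. The tests of a common detection threshold and of CRISPR after strandless subtraction were set before their values were seen, and the latter is void.

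Between 24 h and 4 h of recovery, 4 named features were called in limma, and that call is why they are listed here. The log2 differences were -1.54 for CRISPR1, 1.79 for CRISPR2, -1.45 for CRISPR3 and 3.11 for LEADER2. CRISPR2 was not called with no filter (1.01). CRISPR3 was not called with no filter (-0.33), the strict filter (-0.72), the mean of its probes (-0.73) or the deposited table (-0.91). Over all groups, exact permutation tests gave p = 0.00625 for CRISPR3 (adjusted p = 0.0104) and p = 0.000673 for LEADER2 (adjusted p = 0.00337). These tests include growing and starved cells and ignore slide, so they do not test recovery time alone. A control probe, E1A_r60_a104, which no comparison used, gave at least 8.01 times the signal of the negative control spots on each of the 11 arrays.

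CRISPR1 and CRISPR2 moved apart in starved cells and back together in recovery. The groups differed in CRISPR1 minus CRISPR2 in an exact permutation test (p = 0.00269, adjusted p = 0.00673). A scale factor cancels in that difference, which changed by 3.66 from growing to starved cells against a pooled SD of 0.22, so array scaling is excluded. Slide alone is excluded because the difference changed by -3.33 between 4 and 24 h on 1 slide. With strandless signal subtracted the change was 4.90, which decides nothing, because CRISPR2 was the dimmer feature in starved cells and subtraction lowers it most. An added signal only raises probes, so it does not account for the change of -1.81 in CRISPR2 over the kept probes, where a signal at the strandless level would raise the array scale by 0.17 log2. For CRISPR1 the yardstick was the rise of the dimmer strand of complementary pairs. On both starved arrays the median rise of the kept CRISPR1 probes was at least 4.89 times the 95th percentile of that rise. This argues against an added signal of the size seen in those pairs. It cannot exclude a larger one on CRISPR1. All 49 CRISPR1 probes share their first and last bases, while probes of the pairs have no other partner. The CRISPR2 change in starved cells depended on the filter, at 0.46 with no filter and -3.18 over probes well above background on all arrays.

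CRISPR3 lay below growing cells at 24 h, on another slide. The fall of -1.45 from 4 to 24 h was within 1 slide, so a constant slide offset does not account for that step. That step was not called with no filter (-0.33), with the strict filter (-0.72), with the mean of the probes (-0.73) or in the deposited table (-0.91). With the strict filter, CRISPR3 changed by -1.53 in starved against growing cells, within slide 1. For the gap to growing cells, slide and group cannot be told apart, since no growing array lies on slide 2. A biological difference stays open as well.

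The starved arrays were flatter. Complementary probes differed by a median of 1.73 and 1.35 log2 on the starved arrays and 1.99 and 1.87 on the growing arrays, and 12 h replicate 2 was also low at 1.64. Groups did not separate beyond the spread of arrays in an exact permutation test (p = 0.103, adjusted p = 0.129). At 1 common threshold the lower starved array still exceeded the higher growing array by 12.0 percentage points of probes, which argues against the detection threshold as the cause of that gap. On 12 h replicate 2 the share was 66.5%, above 65.9% on starved replicate 1, and the share of probes well above background did not separate the groups in the permutation test (p = 0.296, adjusted p = 0.296). Dim complementary probes correlated more on both starved arrays than on any other, by at least 0.106, consistent with a signal without strand such as carried-over DNA, though broad transcription of both strands was not tested. Non-specific binding stays open, because negative controls rose by 0.489 of the rise of dim probes on average but by 0.835 on one starved array and -0.355 on the other. With strandless signal subtracted, starved against growing had 16966 calls, 7702 higher and 9264 lower, the opposite of the split before subtraction. That turn decides nothing, because the subtraction itself took more from the starved than from the growing arrays.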

How the results depend on the processing

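CRISPR1 and LEADER2 in starved against growing cells and from 4 to 24 h kept their direction and call in all 23 alternatives run for each, with CRISPR1 from 1.51 to 2.09 and from -1.66 to -1.24 and LEADER2 from -4.26 to -3.36 and from 2.64 to 3.39. The 4 numbered probes kept theirs in 22 alternatives each. Dim probes limited the other features. With no filter CRISPR2 changed by 0.458 in starvation, -0.104 at 12 h and -0.045 at 24 h against starved cells, signs opposite to the main values of -1.81, 1.08 and 1.70, because that setting takes the median over 55 probes in place of 26. With only probes above background on all arrays CRISPR3 at 48 h against starved cells was 0.167, where fewer probes enter. The cause of the moves below was not tested except where named.

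With normexp, starved against growing had 13791 calls, 4 h and 24 h against starved 8380 and 14166, 12 h against 4 h 4026, 24 h against 12 h 2978, 24 h against 4 h 8365, 48 h against 24 h 484 and 24 h against growing 1970, and the share reversed was 84.16%. With only probes above background on all arrays, where 27322 features were tested, these were 10005 for starved against growing, 6504, 10583, 10677 and 9231 for 4, 12, 24 and 48 h against starved, 3330 for 12 h against 4 h, 3038 for 24 h against 12 h, 7359 for 24 h against 4 h, 456 for 48 h against 24 h and 2201 for 24 h against growing, and 84.64% reversed. In the deposited table they were 12476 for starved against growing, 8589, 13478 and 13757 for 4, 12 and 24 h against starved, 3942 for 12 h against 4 h, 2846 for 24 h against 12 h, 8270 for 24 h against 4 h, 424 for 48 h against 24 h and 1775 for 24 h against growing. With no minimum fold, which admits smaller changes, they were 21991 for 4 h against starved, 11757 for 12 h against 4 h, 10119 for 24 h against 12 h, 23287 for 24 h against 4 h and 10370 for 24 h against growing.

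The 48 h counts moved most often. For 48 h against 24 h they were 404 with quantile normalization, 63 with no filter, 514 with an intensity trend and 391 with strandless signal subtracted, an alternative chosen after seeing the data. Slide 2 alone gave 0 calls in limma, with 5168 features at an unadjusted p under 0.05. For 48 h against growing they were 67 with no filter and 1386 with an intensity trend. Only the 2 groups compared gave 3471 for 24 h against 12 h. The share reversed was 81.29% after quantile normalization, 80.59% with strandless signal subtracted and 71.42% over all features.

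Replicate numbers did not pair the samples across all groups, since the replicate differences of only 3 of 10 pairs of groups correlated over 0.1. The correlations ran from -0.13 to 0.30. Those 3 were starved cells with 12 h (0.30), starved cells with 24 h (0.13) and 12 h with 24 h (0.27), so pairing among these groups stays open. With the replicate number as a block, 48 h against 24 h had 96 calls and 48 h against growing 424, and no other count moved by over 1.5 times. With each replicate left out, and the lone array of its group assumed to vary like the others, counts ran from 1 to 254 for 48 h against 24 h, from 34 to 756 for 48 h against growing, from 1925 to 5939 for 24 h against growing and from 3718 to 7069 for 24 h against 12 h, and the share reversed from 81.19% to 85.31%.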

Other observations

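Probes on opposite strands were compared after the data were seen. Of 778 pairs in which the target of one probe has an open reading frame only on that strand and the target of the other has none, 388 had both probes fitted. An open frame over 1 probe does not establish a coding strand, since 94.9% of all targets and 82.6% of their complements had one. In starved against growing cells, 178 of the probes with the open target were higher and 30 lower. Of their partners on the opposite strand, 222 were higher and 20 lower. Both probes were called in the same direction in 109 pairs, where independent lists would give 103.4, and in opposite directions in 29, where they would give 26.3. The changes of the 2 strands had a Pearson's r of -0.00047 and a Spearman's rho of 0.05 across pairs. By comparison, 596 pairs of probes overlapping on 1 strand, of any sequence class, had a Pearson's r of 0.92. From 4 to 24 h, opposite strands had a Pearson's r of -0.13. They were called in the same direction in 29 pairs, where independent lists would give 29.6, and in opposite directions in 22, where they would give 16.0. Probes are not independent replicates, and no p-value is given.

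Some features changed in opposite directions over the 2 steps from starved cells to 4 h and from 4 to 24 h. Higher and then lower were 1837, where independent lists would share 872.3, and 1604 of these were also called higher at 4 h than in growing cells. Lower and then higher were 1325, where independent lists would share 970.1, and 1053 of these were also called lower at 4 h than in growing cells. Unchanged groups simulated in 20 draws gave 0 on average, a value that leaves out the real effects in both steps and so supports neither count. The steps share the 4 h arrays, so part of each count can come from them, and the first step crosses slides.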
